A study of Mus musculus with 4 samples.

How the data were processed

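Total RNA of mouse bone marrow-derived dendritic cells was measured on Affymetrix Mouse Gene 1.0 ST arrays, per the labels. Bone marrow cells were cultured in medium with 10% serum and 20 ng/mL GM-CSF, and siRNA was introduced by electroporation on day 10. LPS at 100 ng/mL was added 24 hours after transfection, and cells were harvested 24 hours later, per the labels' protocols. The 4 conditions, control or NR4A3 siRNA without or with LPS, have 1 array each. The labels give the mouse strain as BALB/c in the growth protocol and as C57BL/6 in the sample descriptions.

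The deposited values are log2 expression values made by RMA with quantile normalization, per the labels, and the submitters' processing notes name Affymetrix Expression Console 1.1. The design text also names GeneSpring. Any filter applied before deposit and the genome build are not given in the sources used here, so no coordinates are printed. Values ran from 4.21 to 14.27, and the medians of the 4 arrays differed by little, so no further scaling was applied for the main results. Quantile normalization gives all arrays 1 distribution, so a shift of most genes in 1 direction would not be visible.

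Probe sets were named from the platform annotation. Of 28856 probe sets, 21789 had 1 gene symbol, 1621 had several and 5446 had none here. The last 2 kinds, 7067 probe sets, were not used for genes. Gene identifiers of 21698 single-symbol probe sets were found in the RefSeq gene table, and 0 symbols needed an update. This gave 19938 genes, of which 999 had several probe sets and were taken at the probe set with the highest mean over the 4 arrays. Genes with near-identical copies (such as the Cd209, Klri, Klk1b and Ifi200 families) are uncertain where copies could share probes.

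A comparison of 2 arrays leaves no residual degrees of freedom, so it has no test. Each comparison is the log2 difference between 2 arrays, and folds are its power of 2. The comparisons were LPS against unstimulated under either siRNA and NR4A3 against control siRNA in either state. A gene was counted when its difference was at least 2-fold and its brighter array of the pair reached the median of the named genes over all arrays, 6.66. The number of arrays limits the precision of every value. The direction of silencing without and with LPS, and that of LPS under either siRNA, was compared at 1.5-fold between pairs that share no array, with the number shared by independent lists (the product of both counts over the number of genes). The difference of the LPS effects was taken over all 4 arrays. An additive fit of siRNA and LPS (limma's lmFit and eBayes, 3 coefficients and 1 residual degree of freedom, Benjamini-Hochberg, adjusted p under 0.05) was added after the results were seen, over the 10592 genes with at least 1 array at 6.66. It tests each average effect against a residual made of the difference of LPS effects and array noise, with a prior of 4.76 degrees of freedom estimated over genes. The labels do not say that the arrays came from separate cultures, so its p-values measure the spread between these arrays only.

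Before the data were examined, 37 gene lists were written for pathways of dendritic cells and LPS signalling and for markers of cell types that such cultures can hold. Of their 650 entries, 585 were measured. For 35 lists with at least 5 members measured, the median difference was placed among 10000 random lists of the same size, drawn within 20 bins of mean level. A list was called outside when its median lay beyond the central 95%. This describes these arrays only: members of a list are regulated together, so such a range is narrower than the spread between repeated cultures would be. Of 140 pairs of list and comparison, 65 lay outside.

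The genes named in the text follow a rule also written beforehand: Nr4a3, the 10 most higher and 10 most lower genes of each comparison past the filter and 2-fold, up to 4 members of each list with the largest differences, the 10 genes per direction with the largest smaller difference among those that silencing moved the same way in both states, and the 8 largest per direction for the difference of LPS effects. Symbols of gene models, RIKEN clones, small RNAs, olfactory and vomeronasal receptors, pseudogenes and antigen receptor segments were left out. Genes with opposite directions, and H2-Ea for the question of strain, are named in addition.

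Alternatives fixed before the data were examined were median centring, a repeated quantile normalization over the named genes, cyclic loess between arrays, other fold thresholds (1.5-fold and 3-fold), no filter or one at the 75th percentile (8.67), the mean of a gene's probe sets, and for lists random lists not matched on level, members above the filter alone and the median without the farthest member. The counting was run on simulated data with known changes, as a check of the code alone, since without replicates the noise between cultures is unknown. In the same simulated data, where LPS had no effect, 3.5% of 200 random unshifted lists lay outside the central 95% for LPS with control siRNA. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.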

Results

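Gene expression was measured in mouse dendritic cells grown from bone marrow with GM-CSF, a growth factor that drives myeloid precursors towards this cell type. The cells received a control siRNA or an siRNA against NR4A3, an orphan nuclear receptor that acts as a transcription factor, and were then left unstimulated or given 100 ng/mL LPS, the bacterial cell wall component sensed through TLR4. The 4 conditions were each measured on 1 array, so a difference between 2 arrays has no replicate check and no p-value. The average effects of silencing and of LPS over all 4 arrays were tested, as given below. Each array held 28856 probe sets, and 19938 genes could be named. Median levels of the 4 arrays lay between 6.37 and 6.42 on the log2 scale. Across probe sets, Pearson's r was 0.993 between the siRNAs in either state, and 0.978 and 0.979 between LPS-treated and unstimulated cells with control siRNA and NR4A3 siRNA.

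The targeted gene was lower with its siRNA in both states. Nr4a3 stood at 11.21 (log2) in unstimulated cells with control siRNA and at 7.15 with NR4A3 siRNA, a 16.6-fold lower level, which ranked 2nd from the lowest of 10257 genes. With LPS the levels were 11.77 and 9.39, a 5.21-fold lower level that ranked 10th from the lowest of 10210 genes. LPS-treated cells with NR4A3 siRNA held 4.71-fold more Nr4a3 signal than unstimulated cells with the same siRNA, while the LPS difference was 1.47-fold with control siRNA. Of the other members of the family, Nr4a1 stayed between 6.74 and 6.85 on all 4 arrays. Nr4a2 was 1.24-fold lower with NR4A3 siRNA in unstimulated cells and 2.28-fold lower with LPS, from 9.79 to 8.60. With LPS the Nr4a2 level was 3.99-fold higher under control siRNA and 2.17-fold higher under NR4A3 siRNA. The median of these 3 family members differed by -0.31 and -1.19 between the siRNAs without and with LPS, and by 0.56 and 1.12 between LPS and no LPS with control and NR4A3 siRNA.

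**Figure D1:**
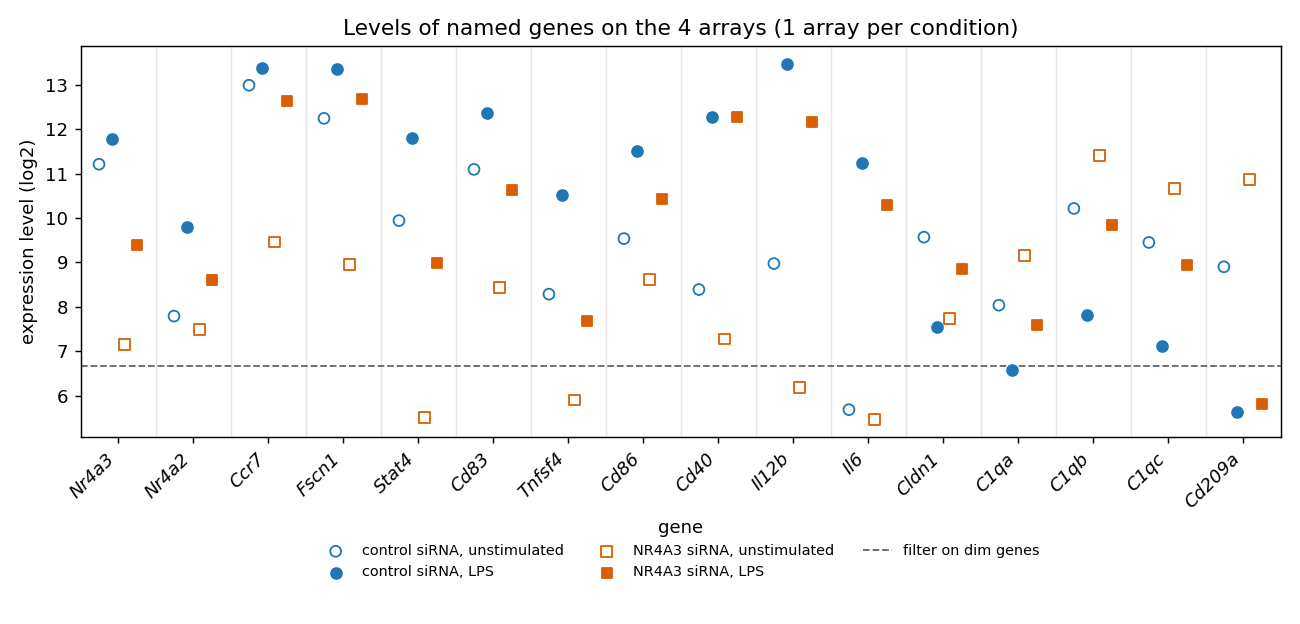
Expression levels (log2, vertical axis) of 16 named genes on the 4 arrays, with circles for control siRNA, squares for NR4A3 siRNA, open symbols for unstimulated and filled symbols for LPS-treated cells, 1 array each; the dashed line is the filter on dim genes at 6.66. Nr4a3 lies at 11.21 and 7.15 in unstimulated cells with control and NR4A3 siRNA, and Ccr7 at 12.99 and 9.46.

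The comparison of the siRNAs in unstimulated cells addresses what NR4A3 contributes to dendritic cells before a microbial signal. Most large differences were towards lower levels with NR4A3 siRNA. Genes of mature, migrating dendritic cells stood out among them. Ccr7, the chemokine receptor that guides dendritic cells to lymph nodes, was 11.6-fold lower, from 12.99 to 9.46. Fscn1, the actin-bundling protein of dendrites, was 9.81-fold lower, from 12.24 to 8.95, and the maturation marker Cd83 was 6.29-fold lower. Stat4, a transducer of interleukin-12 signals, had the largest difference of all, at 21.7-fold lower, and its level of 5.50 with NR4A3 siRNA lay below the filter on dim genes, as did those of Strip2 and Rerg, so that their folds are approximate. Besides Stat4, Nr4a3, Ccr7 and Fscn1, the 10 lowest genes were Clu (9.45-fold), Strip2 (9.42-fold), Rerg (8.39-fold), Mmp25 (7.49-fold), Ramp3 (7.35-fold) and Nudt17 (7.0-fold). In the other direction the differences were smaller. Cd209a, a C-type lectin of immature dendritic cells, was 3.93-fold higher with NR4A3 siRNA, and its close relative Cd209d was 3.23-fold higher, although probes of such near-identical copies could share signal. The complement genes C1qc and C1qb were 2.33-fold and 2.28-fold higher. Dnmt3aos (3.26-fold), Npepl1 (2.97-fold), Rnf144b (2.52-fold), Ptbp2 (2.51-fold), Dbp (2.35-fold) and Rgl1 (2.28-fold) completed the 10 highest. In all, 176 genes were at least 2-fold lower and 21 at least 2-fold higher among 10257 that passed the filter, so that 89.3% of these genes were lower. The size of the difference had a median of 0.15 and a 95th percentile of 0.65 on the log2 scale over the same genes.

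Gene lists fixed in advance showed which groups were lower. Of 16 genes of co-stimulation and maturation, 8 were at least 1.5-fold lower with NR4A3 siRNA and 0 higher, with a median difference of -0.52 against a central 95% of -0.10 to 0.14 for random lists matched on level. Cd83, the OX40 ligand Tnfsf4 (5.22-fold), Cd40 (2.16-fold) and Relb (2.12-fold) had the largest differences of this list, the Tnfsf4 fold being approximate because its level with NR4A3 siRNA, 5.90, lay below the filter. Of 21 genes of dendritic cell migration, 8 were lower and 0 higher, with a median of -0.19. After Ccr7 and Fscn1, the largest differences there were Adam23 (4.41-fold lower) and Marcksl1 (-0.98). The 30 cell cycle genes had the lowest median of all lists, -0.63, with 18 at least 1.5-fold lower and 0 higher. Kif11 (-1.27), Plk1 (-1.23), Bub1 (-1.12) and Top2a (-1.09), which act in mitosis and DNA decatenation, led that list. Type I interferon-stimulated genes had a median of -0.37 over 30 members, of which 6 were at least 1.5-fold lower, led by the antiviral GTPase Mx1 (4.24-fold) and Ifit1 (-0.91). Smaller shifts below the random range were found for interferon-gamma-type GTPases (-0.22, with the GTPase gene Gbp5 at -1.23 and the transcription factor gene Irf8 2.01-fold lower), the NF-kB pathway (-0.21, with Traf1 at -1.52 and Rel at -1.05), MHC class I presentation (-0.18, with Tap1 at -0.58 and Psmb8 at -0.57) and apoptosis and p53 targets (-0.16, with Gadd45b at -1.84 and Pmaip1 at -0.80). In the same comparison macrophage markers had a median of 0.19, above the random range. Mx1, Ifit1 and Gbp5 lay below the filter with NR4A3 siRNA, so their differences are approximate. None of the 12 MHC class I genes reached 1.5-fold, and without its farthest member that list lay inside the random range at -0.14.

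The cytokine and chemokine lists did not shift as a whole in unstimulated cells, although some members differed widely. The median of 19 inflammatory cytokines was 0.05, inside the random range. Il12b, the p40 subunit of interleukin-12, was about 6.91-fold lower, from 8.97 to 6.18, a level below the filter, and Il33 was 2.38-fold lower, whereas Tnf was 1.79-fold higher. With the members above the filter alone, the list median was -0.15 and lay below the random range. The median of 24 chemokines was 0.06. Ccl5 was 4.11-fold lower, Ccl22 was 2.03-fold lower and Ccl7 differed by 0.78. Anti-inflammatory mediators had a median of 0.05, with Aldh1a2, an enzyme of retinoic acid synthesis, 3.92-fold lower and the signalling inhibitor Socs2 at -0.85. MHC class II presentation had a median of -0.04 with H2-Oa at -1.06, and the TLR4 signalling list one of 0.04 with Traf6 at -0.73.

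With LPS, the comparison of the siRNAs addresses what NR4A3 contributes to activated cells. Since Nr4a2 was 2.28-fold lower there too, its differences cannot be assigned to Nr4a3 alone. Lower levels again made up most of the large differences. Klri2, a killer cell lectin-like receptor, was 15.7-fold lower with NR4A3 siRNA, from 10.39 to 6.41, with the reservation that its close relatives could share its probes. Tnfsf4 was 7.15-fold lower, Stat4 was 7.06-fold lower, and Il12rb2, the signalling chain of the interleukin-12 receptor, was 5.93-fold lower. Tcaf2 (6.09-fold), Perp (6.08-fold), Arap2 (5.51-fold), Wfdc9 (5.27-fold) and Rerg (5.23-fold) were the other genes among the 10 lowest besides Nr4a3. With NR4A3 siRNA, Klri2, Perp, Arap2, Wfdc9 and Rerg lay below the filter, so their folds and their order are approximate. C1qb had the largest difference upwards, at 4.07-fold, and C1qc was 3.53-fold higher. They were joined by Dnmt3aos (3.91-fold), Galnt9 (3.84-fold), the pantetheinase gene Vnn3 (3.49-fold), the interferon-induced chemokine Cxcl9 (3.37-fold), the transferrin receptor Tfrc (3.14-fold), Klk1b11 (2.89-fold), Pla2g2d (2.59-fold) and Siglecf (2.58-fold). Klk1b11 belongs to a family of near-identical kallikreins, so its value is uncertain. Among 10210 genes, 171 were at least 2-fold lower and 48 at least 2-fold higher, with 78.1% of these lower. The size of the difference had a median of 0.18 and a 95th percentile of 0.72.

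The co-stimulation and maturation list was again lower with NR4A3 siRNA under LPS, with a median of -0.54 and 8 of 16 members at least 1.5-fold lower. After Tnfsf4, its largest differences were Cd83 (3.31-fold lower, from 12.36 to 10.63), Tnfsf15 (2.37-fold lower) and Cd86 (2.10-fold lower). Cd40 reached 12.28 with either siRNA. Inflammatory cytokines had a median of -0.33 with LPS, with 5 of 19 members at least 1.5-fold lower and 0 higher. Without LPS the whole list lay inside the random range, but below it over the members above the filter alone. With LPS, Il12b was 2.49-fold lower, from 13.47 to 12.16, Il33 was 2.21-fold lower, Il6 was 1.92-fold lower and Il15 was 1.82-fold lower. Tnf and Il1b differed by 0.01 and -0.03. In the same comparison monocyte markers had a median of -0.27, below the random range, with Plac8 2.40-fold lower; without that farthest member their median was -0.17, inside it. Anti-inflammatory mediators had a median of -0.26 with members in both directions, 4 at least 1.5-fold lower, such as Il1r2 (-1.07) and Socs2, and 3 higher, led by Ido1 (0.93). Il10, at -1.24, peaked at 6.11 and so stayed below the filter on all 4 arrays. Dendritic cell migration had a median of -0.29 with 8 of 21 members at least 1.5-fold lower, led here by the chemokine receptor Cxcr4 (2.97-fold), Socs2 (-1.01) and Itga4 (-0.98). The lists of NF-kB (-0.22), interferon-gamma-type GTPases (-0.20), type I interferon-stimulated genes (-0.17), MHC class I presentation (-0.15) and the cell cycle (-0.14) lay below their random ranges. Their medians were nearer to zero than in unstimulated cells, except that of NF-kB, which had been -0.21 there. Few of their members were at least 1.5-fold lower: 5 of 22, 1 of 10, 2 of 30, 0 of 12 and 1 of 30, in the same order. Chemokines had a median of 0.02 with members in both directions, such as Cxcl9 at 1.75 and Ccl24 at -1.10. MHC class II presentation stayed inside the random range at -0.07, although H2-Eb2 was at -1.43, as did the TLR4 signalling list at -0.05, in which Tlr2 was 2.08-fold higher. The differences of Ido1, Ccl24 and H2-Eb2 are approximate, since each lay below the filter on 1 of the 2 arrays.

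The pair of arrays without LPS and the pair with LPS share no array, so the direction of silencing could be compared between them. The labels do not say whether the arrays of an siRNA came from separately transfected cultures. If they did not, a chance difference between the cultures would give agreement as well. Among 10592 genes, 258 were at least 1.5-fold lower with NR4A3 siRNA in both states, where independent lists would share 22.99, and 72 were higher in both, where independent lists would share 6.10. Opposite directions were found for 3 genes, against 25.95 for independent lists. Pearson's r of the differences was 0.646 across genes, which are not independent replicates. The genes lowest in both states, by the smaller of their differences, were Stat4 (-2.82), Rerg (-2.39), Tnfsf4 (-2.38), Nr4a3 (-2.38), Adcy6 (-2.22), Tcaf2 (-2.21), Clu (-2.15), Adgrg6 (-2.11), Castor2 (-1.96) and Strip2 (-1.90). Stat4, Rerg, Tnfsf4, Adcy6, Tcaf2 and Strip2 lay below the filter with NR4A3 siRNA in unstimulated cells, and Rerg with LPS as well, so the sizes and the order are approximate. Those highest in both were Dnmt3aos (1.71), C1qc (1.22), C1qb (1.19), Npepl1 (1.17), the vesicle fusion protein gene Snap25 (1.15), C1qa (1.02), Slamf8 (0.93), Tfrc (0.90), Sowahc (0.90) and Klrb1f (0.87), of which C1qa lay below the filter on 1 array. Other genes differed between the siRNAs mainly without LPS, where Nr4a3 itself was 16.6-fold lower, against 5.21-fold with LPS. With NR4A3 siRNA under LPS, Ccr7 was 1.67-fold lower, from 13.38 to 12.64, and Fscn1 1.58-fold lower, from 13.34 to 12.68. Some compression at such high levels cannot be excluded. Ccl5 was 1.13-fold lower under LPS, but at 14.09 it lay close to the highest value of its array, 14.25, where differences can be compressed.

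**Figure D2:**
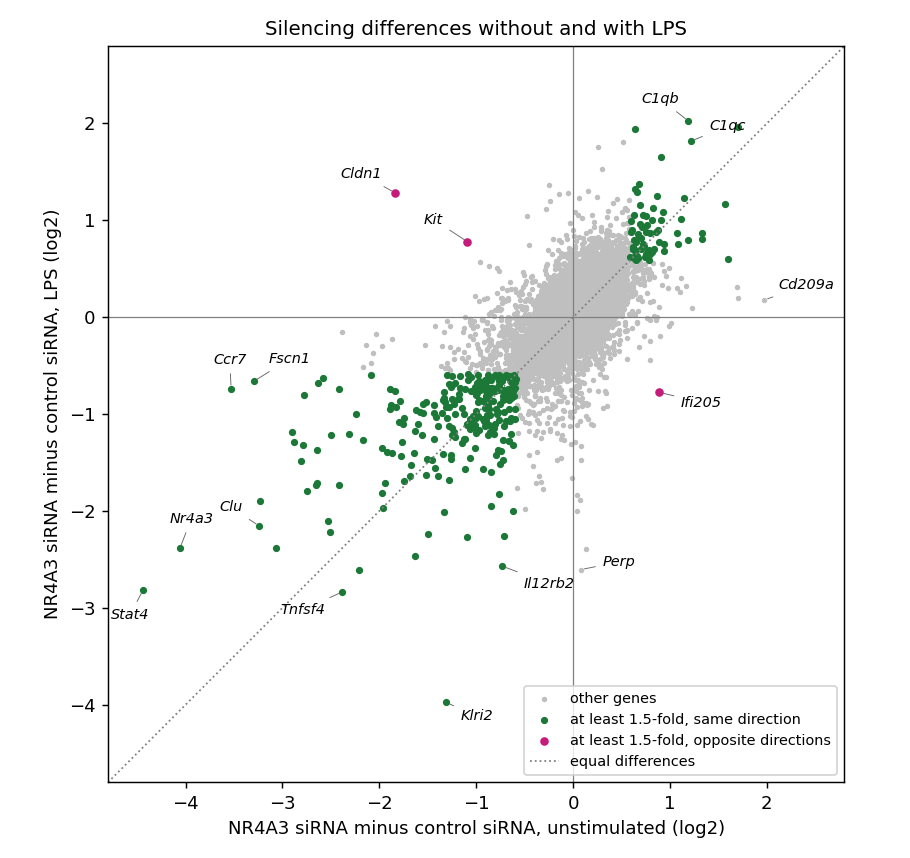
Log2 difference between NR4A3 siRNA and control siRNA for each of 10592 genes, in unstimulated cells on the horizontal axis and in LPS-treated cells on the vertical axis, from 1 array per condition; green points are at least 1.5-fold in the same direction in both, pink points in opposite directions, and the dotted line marks equal differences. The 258 genes lower in both states outnumber the 72 higher in both, and Cldn1, Kit and Ifi205 are the 3 in opposite directions.

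LPS against no LPS in cells with control siRNA addresses the activation response itself. Inflammatory and interferon-induced genes were higher with LPS by large factors. Ms4a4c was 73.9-fold higher, Nos2, the inducible nitric oxide synthase, 60.2-fold, Il6 46.6-fold and the interferon-induced Ifi205 45.7-fold, the last with close relatives that could share its probes. Lcn2 (43.3-fold), the cyclooxygenase gene Ptgs2 (38.8-fold), Susd2 (37.5-fold), Slfn4 (35.2-fold), BC023105 (31.6-fold) and the chemokine Cxcl11 (31.5-fold) were the next. Nos2, Il6, Ifi205, Susd2, BC023105 and Cxcl11 lay below the filter on dim genes without LPS, so their folds and their order are approximate. The mannose receptor gene Mrc1 had the largest difference downwards, at 15.7-fold, followed by Mamdc2 (14.7-fold), the cyclin gene Ccnb2 (11.8-fold), Cd93 (9.95-fold), Cd209a (9.63-fold), the cyclin gene Ccna2 (9.5-fold), F13a1 (8.40-fold), Fcrls (7.98-fold), Serpinb10 (7.66-fold) and Klk1b11 (7.11-fold). The same reservation holds for Mamdc2, Cd209a, F13a1 and Serpinb10, which lay below the filter with LPS. In all, 517 genes were at least 2-fold higher and 396 at least 2-fold lower among 10346. The size of the difference had a median of 0.23 and a 95th percentile of 1.37.

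By gene list, all 30 type I interferon-stimulated genes were at least 1.5-fold higher with LPS, with a median of 2.23 and Ifit2 (26.5-fold) and Rsad2 (4.61) in the lead. The interferon-gamma-type GTPases had a median of 2.55, with Iigp1 at 4.49 and Gbp4 at 4.37. Of 19 inflammatory cytokines, 15 were at least 1.5-fold higher and 0 lower, with a median of 1.45, among them Il12b (22.6-fold), Il1a (2.91) and Il12a (2.31). Of 16 co-stimulation genes, 13 were higher, with a median of 1.41, led by Cd40 (14.8-fold), Tnfsf15 (8.46-fold) and Cd200 (2.58). MHC class I presentation (median 1.12, with Tap1 at 1.91), anti-inflammatory mediators (0.97, with Ptges at 3.71 and Socs1 at 2.51), the NF-kB pathway (0.97, with Cflar at 1.99), chemokines (0.67, with Cxcl10 at 4.70) and TLR4 signalling (0.33, with Tlr1 at 1.60) were above their random ranges. MHC class II presentation was not, at -0.05. Cell cycle genes had a median of -1.03 with 20 of 30 at least 1.5-fold lower, and cholesterol biosynthesis one of -0.99 with 16 of 19 lower, such as Sqle (-1.69) and Cyp51 (-1.47). Phagocytosis and endocytosis receptors (-0.28) and alternative activation genes (-0.33, with Retnla at -2.53 and Arg1 at -1.96) lay below the random range, although Marco was at 3.40 and Nos2 belongs to the second of these lists. Macrophage markers lay below the random range in the same comparison as well, at -0.23. The values of Iigp1, Il12a, Cxcl10 and Marco are approximate, since their unstimulated levels lay below the filter. Dendritic cell migration had a median of -0.17 with 6 members higher, such as Timp1 (1.92), and 3 lower, such as Ccr2 (-2.0). That median lay below the random range, but inside it when random lists were not matched on level.

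In cells with NR4A3 siRNA, LPS against no LPS asks whether the same response took place when the receptor was silenced. Of the 10 genes highest with LPS, 6 were also among the 10 highest under control siRNA, and of the 10 lowest, 7. Ms4a4c was 84.9-fold higher with LPS, Il12b 62.9-fold, Lcn2 50.7-fold, Nos2 50.1-fold, Susd2 46.6-fold, Slfn4 36.4-fold, Cxcl9 35.9-fold, Cd40 32.1-fold, Ifit2 28.8-fold and Il6 28.2-fold. Cd209a was 33.4-fold lower, Fcrls 16.9-fold, Mamdc2 16.0-fold, Mrc1 14.5-fold, Cd209d 10.3-fold, Serpinb10 8.51-fold, Cd93 7.62-fold, Nxpe5 7.51-fold, F13a1 7.11-fold and Slc9a9 6.79-fold. These folds are approximate too where the lower level lay below the filter, as for Il12b, Nos2, Susd2, Slfn4, Cxcl9 and Il6 without LPS and for all of the lowest but Fcrls, Mrc1 and Cd93 with LPS. At least 2-fold differences were found for 550 genes upwards and 281 downwards among 10353. The size of the difference had a median of 0.23 and a 95th percentile of 1.30. Against the control siRNA arrays, which are separate, 837 genes were at least 1.5-fold higher with LPS under both siRNAs, where independent lists would share 109.2, and 568 were lower under both, against 67.8. Directions were opposite for 9 genes, against 174.5, and Pearson's r across genes was 0.894.

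The lists above their random ranges with control siRNA were also above them with NR4A3 siRNA, among those named for the immune response. LPS medians were 2.57 for type I interferon-stimulated genes, 2.54 for interferon-gamma-type GTPases, 1.62 for co-stimulation and maturation, 1.19 for MHC class I presentation, 1.08 for inflammatory cytokines, 1.04 for the NF-kB pathway, 1.02 for anti-inflammatory mediators, 0.53 for chemokines and 0.36 for TLR4 signalling. MHC class II presentation stayed inside the random range at -0.04. Dendritic cell migration had a median of 0.17, inside the random range, with Fscn1 13.3-fold and Ccr7 9.10-fold higher. Medians below the random range were found for the cell cycle (-0.56), cholesterol biosynthesis (-0.62), alternative activation (-0.51, with Pparg at -2.42) and phagocytosis and endocytosis receptors (-0.22). Macrophage markers were just below it too, at -0.14, but inside it with cyclic loess and when random lists were not matched on level.

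**Figure D3:**
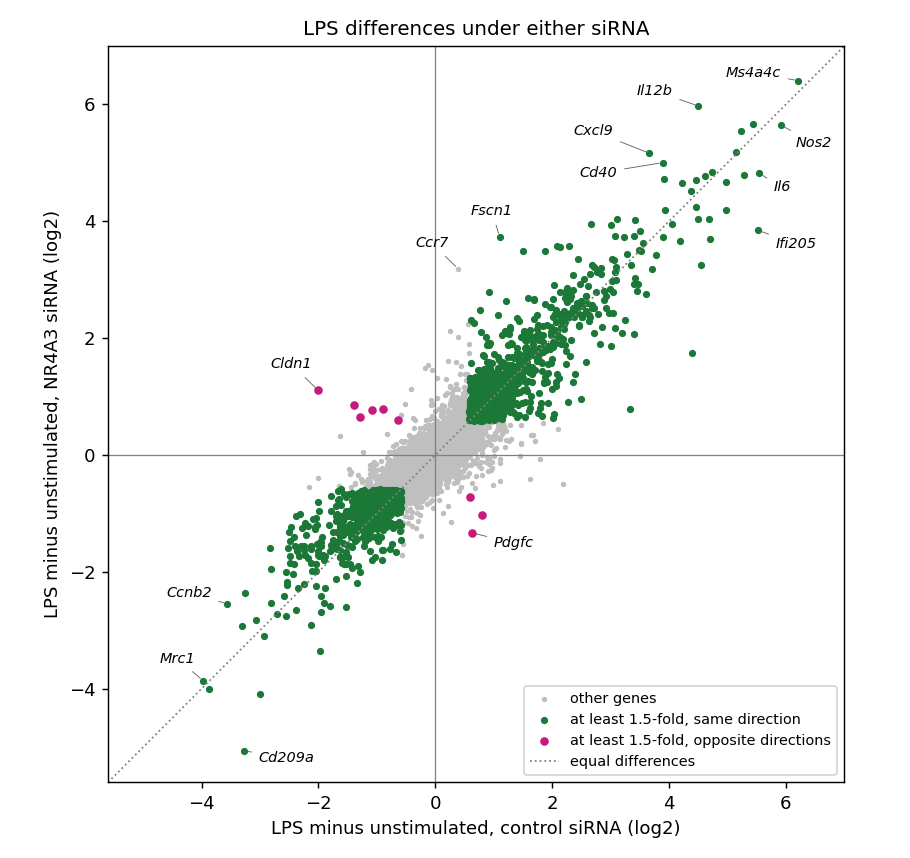
Log2 difference between LPS-treated and unstimulated cells for each of 10592 genes, with control siRNA on the horizontal axis and NR4A3 siRNA on the vertical axis, from 1 array per condition; green points are at least 1.5-fold in the same direction under both siRNAs, pink points in opposite directions, and the dotted line marks equal differences. Most genes lie near the line of equal differences, while Ccr7 and Fscn1 lie above it and Cldn1 is the farthest of the 9 opposite genes.

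The average effects were tested with an additive fit of siRNA and LPS over the 4 arrays (limma's moderated t-test with 1 residual degree of freedom, Benjamini-Hochberg adjustment over 10592 genes), chosen after the differences were seen. Its residual also holds any difference of the LPS effects, so genes whose silencing effect depends on LPS have large errors. At an adjusted p under 0.05, 379 genes were lower and 210 higher with NR4A3 siRNA, and 1653 were higher and 1524 lower with LPS. The silencing counts depend on the filter on dim genes and on the scaling between arrays: they were 132 and 24 with no filter and 223 and 55 with cyclic loess. Nr4a3 had an average silencing effect of -3.22 ± 0.36 (SE, adjusted p = 0.0145), Stat4 one of -3.63 ± 0.35 (adjusted p = 0.0108), Tnfsf4 -2.61 ± 0.13 (adjusted p = 0.0045) and Cd83 -2.19 ± 0.22 (adjusted p = 0.011), each lower in both pairs of arrays, though Stat4 and Tnfsf4 lay below the filter on 1 array. C1qc (1.52 ± 0.16, adjusted p = 0.012) and C1qb (1.61 ± 0.20, adjusted p = 0.0178) were higher in both. Ccr7 (-2.13 ± 0.59, adjusted p = 0.0949) and Fscn1 (-1.98 ± 0.56, adjusted p = 0.0976) did not pass. Of the genes at least 1.5-fold the same way in both silencing pairs, 247 of the 258 lower and 70 of the 72 higher passed, as selection for agreement between the pairs would favour.

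The difference of the LPS effect between the siRNAs asks where silencing and LPS did not simply add up, which a different starting level can also bring about. Silencing itself was not equal in the 2 states: Nr4a3 was 16.6-fold lower without and 5.21-fold lower with LPS. Its weaker lowering with LPS cannot be told apart from a changed LPS effect. The difference of the LPS effect was at least 2-fold in size for 128 of 10592 genes, more positive with NR4A3 siRNA for 69 and more negative for 59. It draws on all 4 arrays and has no error of its own. The most positive differences were Cldn1, a tight junction protein gene (3.12), Ccr7 (2.79), Fscn1 (2.63), P3h2 (2.23), Slamf7 (1.98), Aoc1 (1.96), Ndnf (1.95) and the stem cell factor receptor gene Kit (1.87). Ccr7 and Fscn1 had low unstimulated levels with NR4A3 siRNA, and with LPS their silencing differences were -0.74 and -0.66. Aoc1 and Ndnf passed the filter on 1 array each, and P3h2 and Kit lay below it on 1. The most negative differences were Perp (-2.68), Klri2 (-2.66), Wfdc9 (-2.54), C1ql3 (-2.04), Pdgfc (-1.96), Adig (-1.87), Il12rb2 (-1.83) and Cd209a (-1.80). Perp, Klri2, Wfdc9, C1ql3 and Adig passed the filter with control siRNA and LPS alone, and Pdgfc and Cd209a lay below it on 1 and 2 arrays, so the sizes and the order of these differences are uncertain. Several lists had a median difference of LPS effects outside the random range. Cholesterol biosynthesis (0.40), apoptosis and p53 targets (0.25), glycolysis (0.20) and dendritic cell migration (0.17) were among those above it. Anti-inflammatory mediators (-0.12) and immediate early genes (-0.09) were among those below it. Cell cycle genes had a median difference of LPS effects of 0.51, above the range, with 11 of 30 at least 1.5-fold more positive with NR4A3 siRNA. Their silencing medians were -0.63 without and -0.14 with LPS, and with LPS members such as Kif11, Plk1 and Bub1 lay below the filter under either siRNA, so the lower starting level and compressed low values may account for this difference. Inflammatory cytokines had a median of -0.30, with 5 members at least 1.5-fold more negative, led by Lif (-1.02, above the filter on 1 array), and 1 more positive, Il12b (1.475), which had the largest difference of the list and a low unstimulated level with NR4A3 siRNA.

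**Figure D4:**
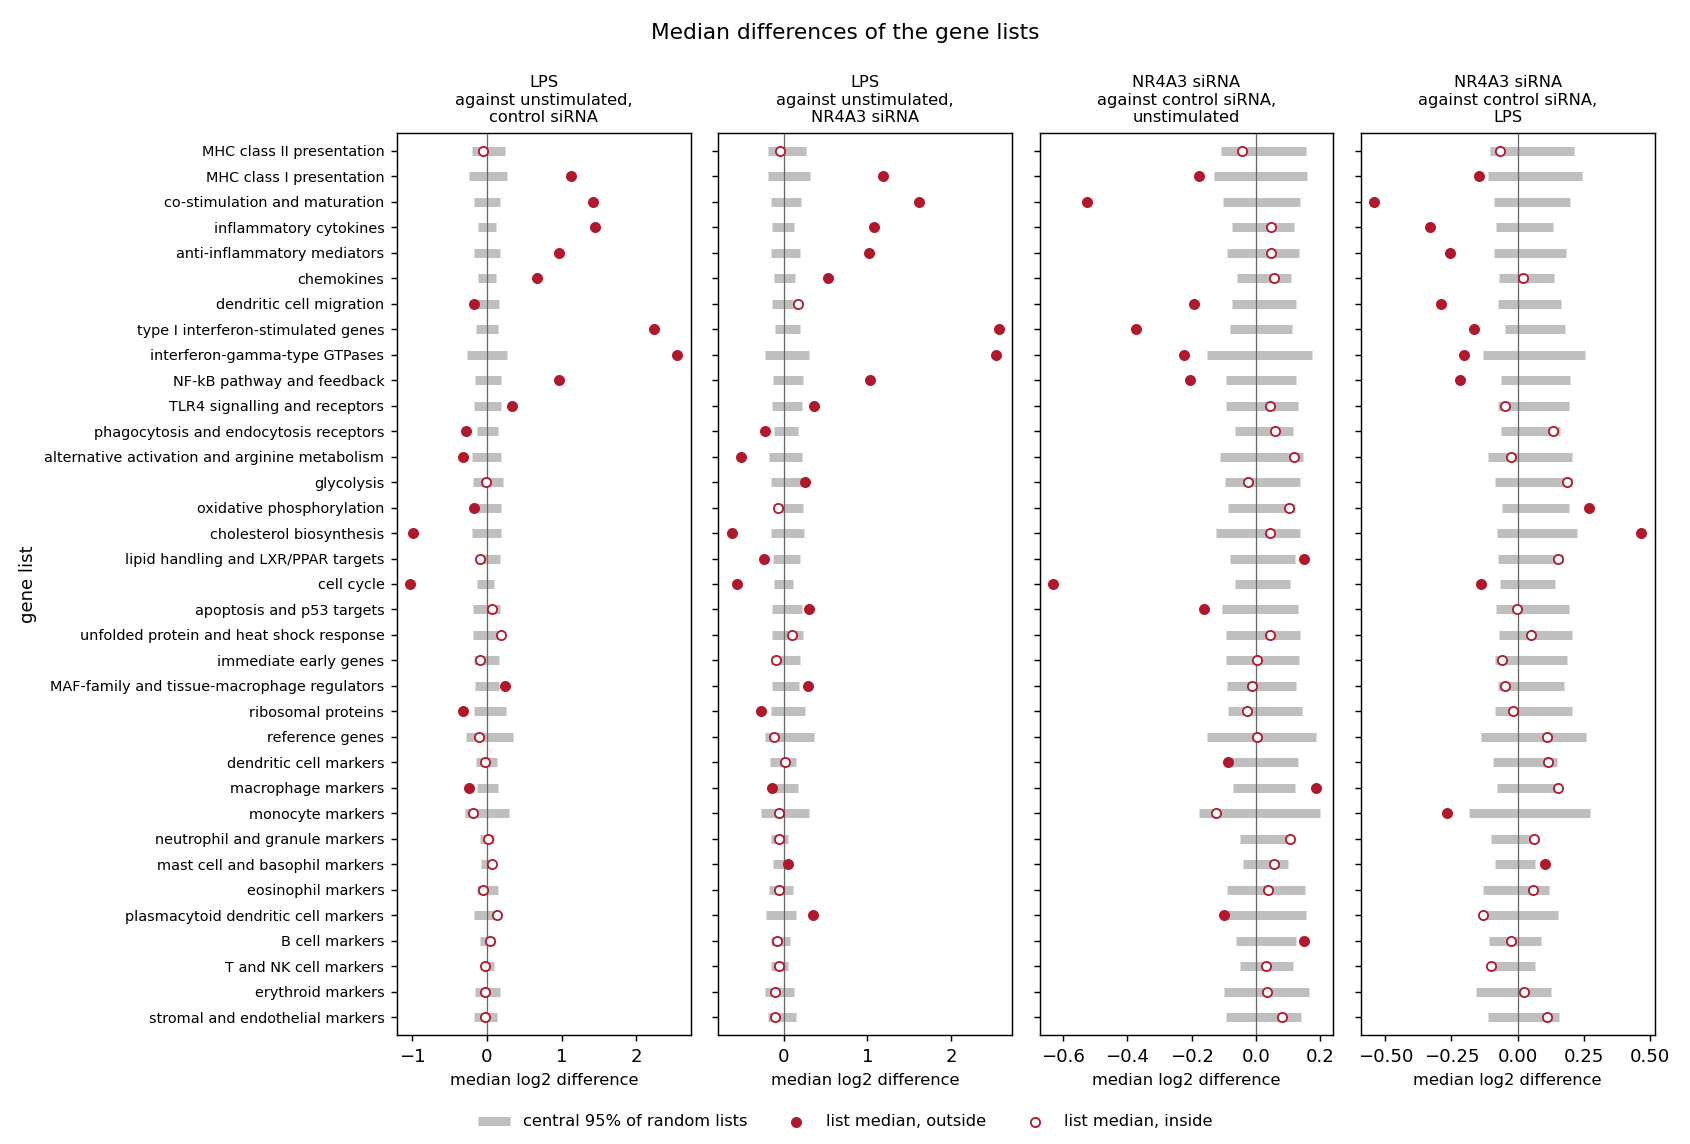
Median log2 difference (horizontal axis, with its own scale in each panel) of 35 gene lists in the 4 comparisons, with filled points outside and open points inside the central 95% of 10000 random lists of the same size and mean level, drawn as grey bars. Co-stimulation and maturation lies at -0.52 and -0.54 in the silencing panels and at 1.41 and 1.62 in the LPS panels.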

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

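Chosen only after the results were seen were the comparisons of dendritic cell markers with Ccr7 and with the lowered genes, the count of lowered genes that stayed lower with LPS, and both tests on the C1q genes.

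Ccr7 was 11.6-fold lower with NR4A3 siRNA in unstimulated cells. An interferon response to the NR4A3 siRNA would raise interferon-stimulated genes, but the 30 measured had a median of -0.37 and a 10th to 90th percentile range of -0.64 to -0.09. Dilution by macrophages, monocytes or neutrophils would lower other dendritic cell transcripts alike, if those cells lacked them. The 13 dendritic cell markers above the filter had a 10th percentile of -0.91 against -3.53 for Ccr7. The marker medians of those 3 cell types were 0.19, -0.12 and 0.11, the first above its random range. This counts against dilution only by cells that lack the dendritic cell markers, since markers that both share would fall by less. The Ccr7 difference was -3.58 under the rescaling that moved it most. However, the rescalings of these already quantile-normalized arrays shifted silencing differences without LPS by at most 0.11, so this check could not have come out otherwise. That NR4A3 may hold up Ccr7 before stimulation is a hypothesis from these data. Fewer cells that matured without LPS stay open, and the marker lists were no test of this. Of 16 co-stimulation and maturation genes, 8 were at least 1.5-fold lower and 0 higher, and with LPS Ccr7 was 1.67-fold lower. An off-target effect of the siRNA, a stronger interferon response to the control siRNA (which would have the sign of that -0.37) and a chance difference between cultures stay open too.

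The 176 genes at least 2-fold lower with NR4A3 siRNA in unstimulated cells held many that LPS raises: 77 of them (43.8%) were at least 1.5-fold higher with LPS under control siRNA, against a median of 8.52% and a central 95% of 4.55% to 12.5% in random lists of like level. The unstimulated control array shared by both comparisons pushes the other way. Genes that LPS lowers were present as well: 38 of the genes (21.6%) were at least 1.5-fold lower with LPS, against 977 of all 10346 genes past the filter. The shared array favours this count and the 977 are not matched on level, so no excess can be read from it. Dilution by cells without the 13 dendritic cell markers would lower these markers by about the median of the 176 genes, -1.33. The markers had a median of -0.04 and a 10th percentile of -0.91. Dilution by cells that share the markers is not excluded by this. Fewer cells that matured without LPS, as the whole cause, would leave few of the genes lower once LPS was given. However, 127 of the 176 (72.2%) were still at least 1.5-fold lower. That threshold is below the 2-fold used to pick them, so the count includes genes whose difference shrank. Ccr7 went from 11.6-fold to 1.67-fold lower and Fscn1 from 9.81-fold to 1.58-fold, whereas Tnfsf4 went from 5.22-fold to 7.15-fold. A part for fewer spontaneously matured cells, for the other 49 genes or those that shrank for example, remains a candidate explanation. So do fewer mature cells with LPS as well, beside an effect of NR4A3 within cells.

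C1qa, C1qb and C1qc were higher with NR4A3 siRNA in both states, by 1.02 at the least, though C1qa lay at 6.58 with control siRNA and LPS, below the filter on dim genes. More macrophages would raise their other markers by like amounts if the other cells in the culture lacked those markers. The 12 others above the filter had medians of 0.17 without and 0.15 with LPS, and 90th percentiles of 0.37 and 0.54. Markers that other cells share would rise by less, and the whole macrophage list lay above its random range without LPS, at 0.19. More macrophages are therefore not excluded. The rescalings left the smallest of these differences at 0.97, but they shifted silencing differences in either state by at most 0.11. This check could therefore not have come out otherwise. A change of state in macrophages or dendritic cells stays open and was not tested; C1qb was 5.25-fold lower with LPS under control siRNA.

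Several genes had LPS differences of at least 1.5-fold in opposite directions under the 2 siRNAs, and for none of them was the difference tested. The difference of LPS effects, NR4A3 minus control siRNA, was 3.12 for Cldn1 (4.03-fold lower with LPS under control siRNA and 2.16-fold higher under NR4A3 siRNA), 2.23 for P3h2, 1.95 for Ndnf, 1.85 for Adam23, 1.68 for Ceacam15 and 1.24 for the proliferation marker Mki67. It was -1.96 for Pdgfc, -1.83 for Il12rb2 and -1.32 for Ndrg1. Ndnf, P3h2, Ceacam15 and Pdgfc peaked at 7.81, 8.22, 7.87 and 8.12 and lay below the filter on at least 1 other array.

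Silencing differences of at least 1.5-fold pointed in opposite directions without and with LPS for 3 genes, again with no test of the difference. Cldn1 was 3.58-fold lower without and 2.44-fold higher with LPS (a difference of 3.12), Kit 2.13-fold lower and 1.72-fold higher (1.87), and Ifi205 1.85-fold higher and 1.71-fold lower (-1.67). Kit and Ifi205 lay below the filter on 1 array each, at 5.88 and 6.62. Ifi205 has close relatives that could share its probes.

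Signal was also present in probe sets without a single gene name, which enter no comparison above. Of 2321 past the filter without LPS, 12 were at least 2-fold lower and 2 higher with NR4A3 siRNA, and of 2265 with LPS, 15 were lower and 5 higher.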

How the results depend on the processing

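All alternatives were fixed before the data were examined, except those of the additive fit. Median centring, repeated quantile normalization, cyclic loess and the mean of a gene's probe sets left every count of differences between arrays recomputed under them within 1.5 times its value, and so did using no filter. The 3 rescalings and the mean of probe sets kept the sign of all 4 Nr4a3 differences and moved them by no more than 0.2 on the log2 scale. They did the same for all 94 differences of the genes named by the size rules, over 376 recomputed values. The deposited arrays were already quantile normalized, and the 3 rescalings moved differences between 2 arrays by at most 0.18. Large differences could therefore hardly have moved further or changed sign, so this says little about their robustness.

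Counts moved with the threshold itself, which by its construction admits more or fewer genes. At 1.5-fold, LPS with control siRNA gave 1058 genes higher and 977 lower, LPS with NR4A3 siRNA 1070 and 712, silencing without LPS 166 and 481, and silencing with LPS 381 and 483. At 3-fold the same comparisons gave 260 and 122, 278 and 80, 5 and 63, and 7 and 44. The filter at the 75th percentile, which removes dimmer genes, left 250 genes lower with LPS under control siRNA and 102 lower with silencing without LPS. A 2-fold threshold in both states left 84 genes with the same silencing direction, against 330 at 1.5-fold. The excess of lower over higher genes with LPS silencing was thus smaller at 1.5-fold than at 2-fold.

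Of 956 list medians recomputed under 7 alternatives, 923 kept their side of the random range, 19 came to lie inside it, 14 came to lie outside it and 0 reversed while outside. The additive fit and its alternatives were chosen after the results were seen. The fit compares the siRNAs within each state, which serves as a block, and leaving out an array would leave it no residual degrees of freedom. Its 210 genes higher with NR4A3 siRNA became 109 with repeated quantile normalization, 55 with cyclic loess, 322 with the mean of probe sets and 24 with no filter, and its 379 lower became 223 with cyclic loess and 132 with no filter. Its other counts, those for LPS included, stayed within 1.5 times their values under these settings, median centring and a prior variance with a trend on level. Genes near the filter at 6.66 and genes near the top of the arrays, such as Ccl5, can have compressed differences.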

Other observations

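The test of strain was fixed before the data were examined, and the correlation of silencing with LPS differences was chosen after the results were seen.

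Metabolic lists differed in the states where their silencing medians lay outside the random range, if at all. Whether silencing acted differently in the 2 states was not tested. Cholesterol biosynthesis genes had a median of 0.47 with NR4A3 siRNA and LPS, where 5 of 19 were at least 1.5-fold higher, such as Hmgcs1 (0.99) and Hsd17b7 (0.85), and 2 were lower, Idi1 (-1.42) and Pmvk (-1.10). Without LPS their median was 0.04. Oxidative phosphorylation genes had a median of 0.27 with LPS, with 0 of 24 at 1.5-fold and Sdhb the largest at 0.55, and of 0.10 without LPS. For LPS itself, their median was -0.18 with control siRNA and -0.07 with NR4A3 siRNA. Glycolysis genes had silencing medians of -0.02 without and 0.19 with LPS, both inside the random range, and LPS medians of -0.01 with control and 0.25 with NR4A3 siRNA. The glycolytic activator Pfkfb3 was at -1.28 with NR4A3 siRNA in unstimulated cells. Lipid handling genes had a median of 0.15 with NR4A3 siRNA in either state, outside the random range without LPS, where Pparg was 1.91-fold higher and Fabp4 was at 0.90. Their LPS medians were -0.10 and -0.24 with control and NR4A3 siRNA.

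Other lists shifted little with silencing. Apoptosis and p53 targets had a median of 0.00 with LPS, and LPS medians of 0.07 with control and 0.30 with NR4A3 siRNA. Phagocytosis receptors had silencing medians of 0.06 and 0.13, and alternative activation genes 0.12 and -0.03, without and with LPS. The unfolded protein and heat shock list stood at 0.04 and 0.05, and immediate early genes at 0.00 and -0.06. The regulators of macrophage identity had medians of -0.01 and -0.05, with Irf8 2.01-fold and 2.29-fold lower and Irf4 1.58-fold and 2.42-fold lower. Ribosomal protein genes had silencing medians of -0.03 and -0.02 and LPS medians of -0.33 and -0.27. Reference genes had silencing medians of 0.00 and 0.11. LPS medians with control and NR4A3 siRNA were 0.18 and 0.10 for the unfolded protein list, -0.09 and -0.09 for immediate early genes, 0.24 and 0.29 for the regulators of macrophage identity, and -0.11 and -0.11 for reference genes.

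Markers of cell types had silencing medians between -0.27 and 0.19. Macrophage markers stood at 0.19 without LPS, above the random range, and 0.15 with LPS, inside it. Dendritic cell markers stood at -0.09 and 0.11, with Cd209a at 1.97 and Dpp4 at -0.98 without LPS, and monocyte markers at -0.12 and -0.27, the latter below the random range, with Plac8 2.40-fold lower with LPS. The value of -0.09 came to lie inside the random range under 4 of the alternatives. Neutrophil markers had medians of 0.11 and 0.06, eosinophil markers 0.04 and 0.06, mast cell and basophil markers 0.06 and 0.10, plasmacytoid dendritic cell markers -0.10 and -0.13, B cell markers 0.15 and -0.02, T and NK cell markers 0.03 and -0.10, erythroid markers 0.04 and 0.02, and stromal and endothelial markers 0.08 and 0.11. Of these, B cell and plasmacytoid dendritic cell markers lay outside the random range without LPS and mast cell and basophil markers with LPS, and each of the 3 lay inside it when random lists were not matched on level. Most members of the neutrophil, mast cell, B cell, T cell, eosinophil and erythroid lists lay below the filter on dim genes, 13 of 17 in the neutrophil list for example. LPS medians were -0.23 with control and -0.14 with NR4A3 siRNA for macrophage markers, both below the random range, -0.03 and 0.02 for dendritic cell markers, and -0.18 and -0.06 for monocyte markers. The dendritic cell value with control siRNA was -0.47, below the random range, over the members above the filter alone. Plasmacytoid dendritic cell markers (0.35) and mast cell and basophil markers (0.05) lay above the range with LPS and NR4A3 siRNA, and inside it without their farthest member. Of the sex-linked genes, Xist lay between 10.77 and 11.52 on the 4 arrays, while Kdm5d, Uty and Eif2s3y stayed below 5.

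The labels give 2 strains. C57BL/6 mice do not transcribe H2-Ea, an MHC class II alpha chain gene, and BALB/c mice do. Its level was 13.48 at the lowest and 13.62 at the highest over the 4 arrays, where the 90th percentile of named genes was at most 10.24. The level is consistent with BALB/c cells, as the growth protocol states, though probes shared with related class II genes could add to it.

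Across 10592 genes, silencing and LPS differences went in opposite directions on average. Pearson's r was -0.15 between silencing without LPS and LPS with control siRNA, with a covariance of -0.035. It was -0.18 between silencing with LPS and LPS with NR4A3 siRNA, with a covariance of -0.040. Each pair of comparisons shares an array, whose noise adds a positive covariance of at most 0.022, the value if all of the variance of the difference of LPS effects were noise.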
